A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

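Total RNA of 3 strains of the haploid budding yeast Saccharomyces cerevisiae SEY6210 was compared on 8 Agilent arrays with Cy3 and Cy5 channels. The strains were wild type, a mutant disrupted at PDR5 and YOR1 by hisG cassettes (the double mutant), and a mutant with a further kanMX4 disruption of PDR1 (the triple mutant). Per the labels, cells grew in YPD at 30 °C, RNA was extracted with hot acidic phenol, and aminoallyl cDNA was coupled to the dyes. In each comparison 4 arrays were hybridised: the double mutant against wild type, and the double mutant against the triple mutant. On arrays 1 and 3 of each comparison the double mutant carried Cy5, and on arrays 2 and 4 it carried Cy3.

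The authors scanned the slide and extracted it with Agilent Feature Extraction 10.7.3.1. Per the file headers, the files hold for each spot and channel a mean pixel intensity, a local background intensity, a processed intensity and 0 or 1 flags for spots well above background, saturated or non-uniform, the other columns used. The deposited processed intensity had been detrended and dye-normalised by the authors. The deposited table of normalized log ratios was not used, because the names of its 8 value columns match no array's title or description.

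Mean signals were background-corrected by the normexp method with an offset of 50 and scaled within each array by loess, using limma 3.58.1 in R 4.3.3. Control spots had no weight in the loess curve, and spots marked as outliers were set to missing. The design holds 13092 probes for 6546 features, 2 probes for most features, beside 536 control spots. Names came from the supplied table of locus tags for 5978 features, and the other 568 kept the name on the array. A probe was kept if it stood well above background in at least 4 of the 16 channel measurements, which kept 12872 probes. Each of 6465 genes was then represented by its brighter probe, and 81 features were left out as dim.

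A linear model was fitted to the 8 arrays with limma, with a dye term common to all arrays and 1 coefficient per comparison, leaving 5 residual degrees of freedom. Ratios are the double mutant over wild type, and the channel labelled double mutant over the channel labelled triple mutant. The triple mutant was set against wild type through the double mutant, as the difference of both coefficients. Genes with a Benjamini-Hochberg adjusted p below 0.05 from limma's moderated test were called. The labels do not say whether the arrays of a comparison came from separate cultures, so the p-values measure the spread between these arrays alone. The number of arrays limits the precision.

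Before the data were examined, 30 gene lists were fixed, of which 29 could be built; the list of Ty elements could not, since the reference names none. Each list was tested against the other genes with camera at a preset inter-gene correlation of 0.01, and adjusted over the 29 lists. Camera with an estimated correlation and fry, which tests whether a list's own genes move 1 way on balance, were run beside it. For these tests 60 missing spots were filled with the mean of the other arrays of the comparison. The genes named in the text were fixed by a rule: the 3 disrupted genes; the 10 highest and 10 lowest other called genes with 1 sign on all 4 arrays; up to 3 called members in each direction from each list discussed; and the neighbours of the disrupted loci with the auxotrophic markers. Of the genes the rule takes, 1 is not reported here. Any other gene named is said to have been chosen after its values were seen.

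The procedure was tested on simulated data with 200 changed genes among 6465. In the comparison with wild type it recovered 79% of changes of 0.5 and 98% of changes of 1 on the log2 scale, with 11 unchanged genes called. In the comparison with the triple mutant these values were 86%, 97% and 7. No recovered change had the wrong sign, the shifted list was found, and 0 unshifted lists were called. The simulated genes varied independently of each other, with a dye effect common to all arrays. The list result therefore does not test camera where genes of a list vary together. In the data the estimated correlation was 0.883 in the amino acid synthesis list. Each simulated gene also had the same spread on every array, whereas the quality weights estimated for the real arrays ran from 0.158 to 5.68. The recovery therefore does not describe a fit to arrays of unequal spread.

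Alternatives tried were other background corrections, scalings within and between arrays, filters on dim probes, the mean over the probes of a gene, a fit without the dye term or with the 4 arrays of a comparison alone, replicate numbers or dye-swap pairs as blocks, dye-swap pairs averaged, array quality weights, and leaving out each array in turn. Chosen after seeing the data were a dye term per comparison, the averaging of arrays 1 and 3 and of arrays 2 and 4, and the comparison with the triple mutant turned in sign.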

Results

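Transcript levels of 6465 yeast genes were compared between strain pairs on 8 arrays, 4 for the double mutant (pdr5 yor1) against wild type and 4 for the double mutant against the triple mutant (pdr5 yor1 pdr1). PDR5 and YOR1 encode ABC transporters of the plasma membrane that export drugs and lipids, and PDR1 encodes the transcription factor that drives pleiotropic drug resistance genes. The question of the series is how the transcriptome of the double mutant compares with wild type and with the triple mutant. The median signal of an array was 401.7 to 1300.3 intensity units in Cy5 and 116.9 to 1041.8 in Cy3, the lowest being array 2 of the comparison with the triple mutant. Between 91.9% and 98.2% of probes stood well above background in Cy5 and between 85.7% and 98.7% in Cy3. No spot was saturated.

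PDR5 (YOR153W) fell in the double mutant by 2.76-fold against wild type (log2 ratio -1.46 ± 0.228, SD, n = 4; adjusted p = 0.000165), yet its signal stayed between percentiles 84 and 86.1 of all probes. YOR1 (YGR281W) rose 3.84-fold (log2 ratio 1.94 ± 0.18, SD, n = 4; adjusted p = 4.21e-06). The files do not say where the probes lie relative to the disrupted parts of these genes. PDR1 (YGL013C) had a log2 ratio of 0.05 in this comparison (adjusted p = 0.924).

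On the arrays of the comparison with the triple mutant, PDR1 was low in the channel labelled double mutant, the strain in which the labels leave PDR1 intact. Its log2 ratio, labelled double over labelled triple, was -2.36 ± 0.832 (SD, n = 4; adjusted p = 0.00196), from -2.88, -2.81 and -2.63 to -1.12 on array 2. In the channel labelled double mutant 0 of 8 PDR1 values stood well above background, at percentiles of 0.0535 to 8.18, whereas 8 of 8 did so in the channel labelled triple mutant, at percentiles of 32.6 to 47.6. PDR1 was at least 4.8-fold higher in the channel labelled triple mutant. The double mutant's PDR1 lay at percentiles of 36.1 to 47.3 on the arrays shared with wild type. YOR1 lay at percentiles of 87.5 to 90.4 in the double mutant and 57.6 to 70.5 in wild type on those arrays. On the others it lay at 59.7 to 70.2 in the channel labelled double mutant and 85 to 89.5 in the channel labelled triple mutant. PDR1 therefore goes against the strain labels on all 4 arrays. The direction below is kept as labelled, each ratio is named by its channel labels, and the reading with the sign turned is given beside it where a direction is drawn.

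**Figure D1:**
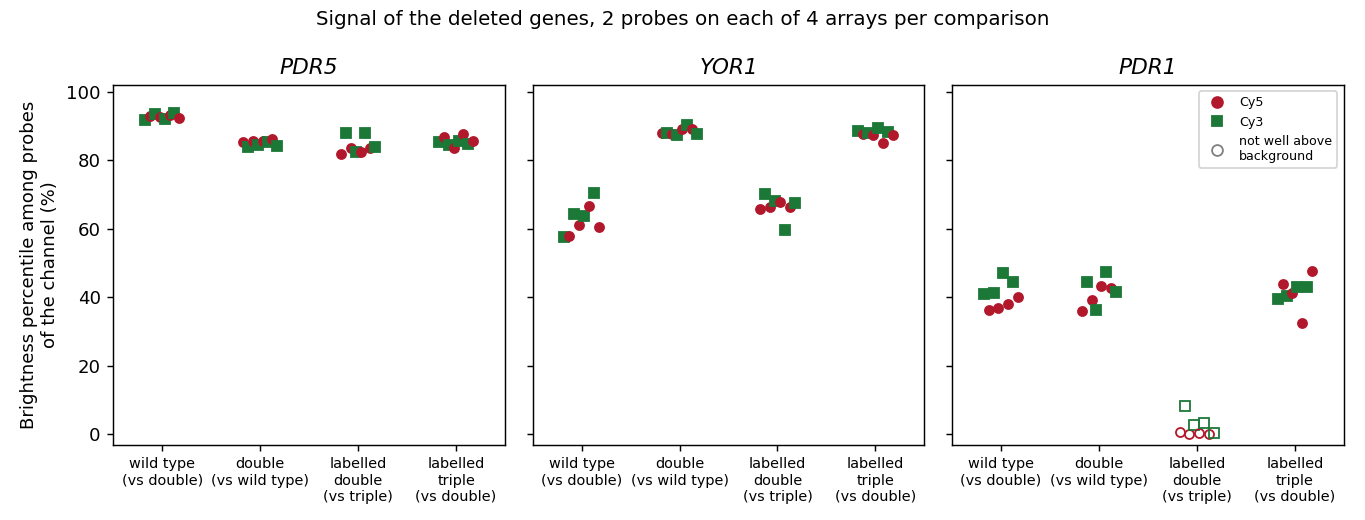
Signal of PDR5, YOR1 and PDR1 in each channel of the 8 arrays, as the percentile among all probes of that channel, with 1 point per probe, grouped by strain as labelled. PDR1 sits at 0.0535 to 8.18 in the channel labelled double mutant and at 32.6 to 47.6 in the channel labelled triple mutant.

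The double mutant was compared with wild type to ask what changes when both transporter genes are disrupted, and genes of the pleiotropic drug resistance (PDR) regulon rose in it. RSB1 (YOR049C), a membrane protein that exports sphingoid long-chain bases, rose 8.54-fold (log2 ratio 3.09 ± 0.316, SD, n = 4; adjusted p = 3.71e-06). ICT1, a lysophosphatidic acid acyltransferase, rose 4.84-fold (2.27 ± 0.134, SD, n = 4; adjusted p = 3.71e-06). GRE2, a methylglyoxal reductase, rose 4.51-fold (adjusted p = 0.000131). Of the 21 measured genes of the regulon 16 rose and 0 fell, with a median log2 ratio of 0.81 (camera adjusted p = 2.71e-17; adjusted p = 0.0342 with an estimated correlation). Adjusted over the list alone, 17 were higher and 1 was lower. Its ABC transporter genes SNQ2, PDR15 and PDR10 rose by log2 ratios of 1.00, 0.50 and 0.36, while PDR12, the carboxylic acid exporter outside the regulon, fell by 0.35. The SNQ2 call was lost without array 1 (0.93), and that of PDR10 in each fit that left out an array but the 1 without array 4 (0.25 to 0.44). The list's median was 0.91, 0.92 and 0.95 on arrays 1, 2 and 3 and 0.51 on array 4.

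Genes of the endoplasmic reticulum's unfolded protein response rose together: 14 of 15 measured genes were called higher, the same number when adjusted over the list alone. The median log2 ratio was 0.39 (camera adjusted p = 2.4e-13; adjusted p = 0.0277 with an estimated correlation). KAR2, the Hsp70 chaperone of the endoplasmic reticulum, rose 1.81-fold (0.85 ± 0.343, SD, n = 4; adjusted p = 0.000406), and SIL1, its nucleotide exchange factor, rose by 0.60 (adjusted p = 0.00178). PDI1, the protein disulfide isomerase, rose by 0.50, a call lost without array 1 (0.56) or array 3 (0.51). The lists of proteasome, sphingolipid and anaerobic genes also shifted upward, by smaller amounts. They passed camera at the preset correlation and not with an estimated one. By fry they passed as well (adjusted p = 0.00186, 0.00563 and 0.0106). RPN4, the transcription factor of proteasome genes, rose by 0.89 (adjusted p = 0.00671). In that list 5 of 32 proteasome genes were called higher, 10 when adjusted over the list alone. The median was 0.14 (camera adjusted p = 2.08e-08; adjusted p = 0.0783 with an estimated correlation). The sphingolipid list had 4 of 32 genes higher, 8 when adjusted over the list alone, among them LAC1, a ceramide synthase (1.01), and SUR2, the sphinganine hydroxylase (0.42), beside RSB1. Its median was 0.11 (camera adjusted p = 1.4e-05; adjusted p = 0.216 with an estimated correlation). In the list of anaerobic and PAU genes 6 of 36 were higher, 9 when adjusted over the list alone. The median was 0.08 (camera adjusted p = 8.07e-06; adjusted p = 0.145 with an estimated correlation). Its examples are the cell wall mannoprotein gene TIR1 (0.89, and 0.54 without array 4), ANB1 (0.41) and HEM13 of heme synthesis (0.38). All 3 calls were lost without array 1 (TIR1 1.02, ANB1 0.39, HEM13 0.34). Those of TIR1 and ANB1 were also lost without array 3 (0.94 and 0.43), and that of TIR1 without any 1 array of the other comparison (0.89).

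Genes of mitochondrial respiration fell: 30 of 35 measured genes were called lower and 0 higher, 34 lower when adjusted over the list alone. The median log2 ratio was -0.42 (camera adjusted p = 1.92e-23; adjusted p = 0.0846 with an estimated correlation). CYC1, encoding cytochrome c, fell 1.57-fold (-0.65 ± 0.169, SD, n = 4; adjusted p = 0.00589), and COR1 of complex III fell 1.54-fold (-0.62 ± 0.0519, SD, n = 4; adjusted p = 0.00497). SDH2 of succinate dehydrogenase had a log2 ratio of -0.64, and -0.43 without array 4. Its call was lost without array 3 (-0.66). In the tricarboxylic acid and glyoxylate cycle 6 of 20 genes were lower, 10 when adjusted over the list alone. The median was -0.22 (camera adjusted p = 2.59e-07; adjusted p = 0.296 with an estimated correlation). The cycle list's median was -0.14, -0.21 and -0.18 on arrays 1, 2 and 3 and -0.51 on array 4. Without array 4 it was -0.15 and 8 genes were lower (camera adjusted p = 2.28e-05). The peroxisomal citrate synthase gene CIT2 had a log2 ratio of -0.77, and -0.57 without array 4.

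Genes of amino acid synthesis under the activator Gcn4 were lower as well, most of all on array 4. Of 41 measured genes 14 were called lower and 0 higher, 32 lower when adjusted over the list alone. The median log2 ratio was -0.50 (camera adjusted p = 6.38e-14; adjusted p = 0.447 with an estimated correlation). The list's median was -0.21, -0.38 and -0.16 on arrays 1, 2 and 3 and -1.51 on array 4. Without array 4 the median was -0.27 and 23 genes were lower (camera adjusted p = 5.25e-15). ARG1, the argininosuccinate synthetase, fell 5.3-fold (-2.40 ± 1.38, SD, n = 4; adjusted p = 0.00631), and by 1.79 on the log2 scale without array 4. The arginine genes ARG3 and ARG4 had log2 ratios of -1.72 and -1.35, and -1.10 and -0.78 without array 4. LEU4 of leucine synthesis had -1.08, and -0.80 without array 4. SNZ1 and SNO1 of vitamin B6 synthesis had -1.82 and -1.83, and -0.997 and -1.13 without array 4. Of the amino acid permeases 5 of 21 were lower, 8 when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.000188; adjusted p = 0.436 with an estimated correlation). Among them SAM3 fell by 0.69 (adjusted p = 0.000406). The sulfur and methionine list had 2 of 25 genes lower, 2 when adjusted over the list alone, both permeases: MUP1 (-0.40), called in 1 of the 8 fits that left out an array, and MMP1 (-0.40), a call lost without array 2 (-0.36) or array 3 (-0.31). The median was -0.26 (camera adjusted p = 0.00686; adjusted p = 0.538 with an estimated correlation). Without array 4 neither list passed the threshold (medians -0.09 and -0.04, camera adjusted p = 0.0716 and 0.423).

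In all, 530 genes differed between the double mutant and wild type, 209 higher and 321 lower, of which 18 and 13 changed at least 2-fold. A total of 1591 genes had an unadjusted p below 0.05. Among the 10 highest, the disrupted genes left aside, were also YGR035C (1.88), CIS1 (1.57), TVS1 (1.55) and the subtelomeric genes YAR066W, YHR214W, YAR068W and YHR214W-A (1.95 to 2.39). The 10 lowest also held ATG41 (-1.49, and -0.95 without array 4), ARO5 (-1.46, and -0.80 without array 4) and ERP1, a cargo receptor of vesicles from the endoplasmic reticulum, which fell 2.27-fold (adjusted p = 0.000406). The calls of SNO1, SNZ1, ARO5, ARG4, ARG3 and ATG41 were lost without array 1 or array 3, and those of the first 4 also without any 1 array of the other comparison. Other called genes were the ferric reductase gene FRE4 (1.11), the iron permease gene FTR1 (-0.53), the hexose transporter gene HXT5 (-0.80), the polyamine transporter genes TPO1 (0.81) and TPO2 (-0.86), the phosphate transporter gene PHO84 (-0.85) and the zinc transporter gene ZRT1 (-0.59). The other 19 of 29 lists, ribosomal proteins and mating-type genes among them, did not pass the threshold in camera. By fry the mating-type and histone lists did pass (adjusted p = 0.0134 and 0.0106). The count was 202 and 309 without arrays 1 and 3, 825 without array 4, and 334, 328 and 324 without arrays 2, 3 and 4 of the other comparison. The 31 changes of at least 2-fold became 19 without array 1. Count and balance depended on the scaling, with 27 higher and 9 lower from the processed signals and 28 higher and 26 lower with median centring. The main fit estimated 1 spread per gene from the arrays of both comparisons. With the 4 arrays of this comparison alone 25 genes were called, 19 higher and 6 lower. Of the named calls, 14 of 89 were kept in every planned setting.

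**Figure D2:**
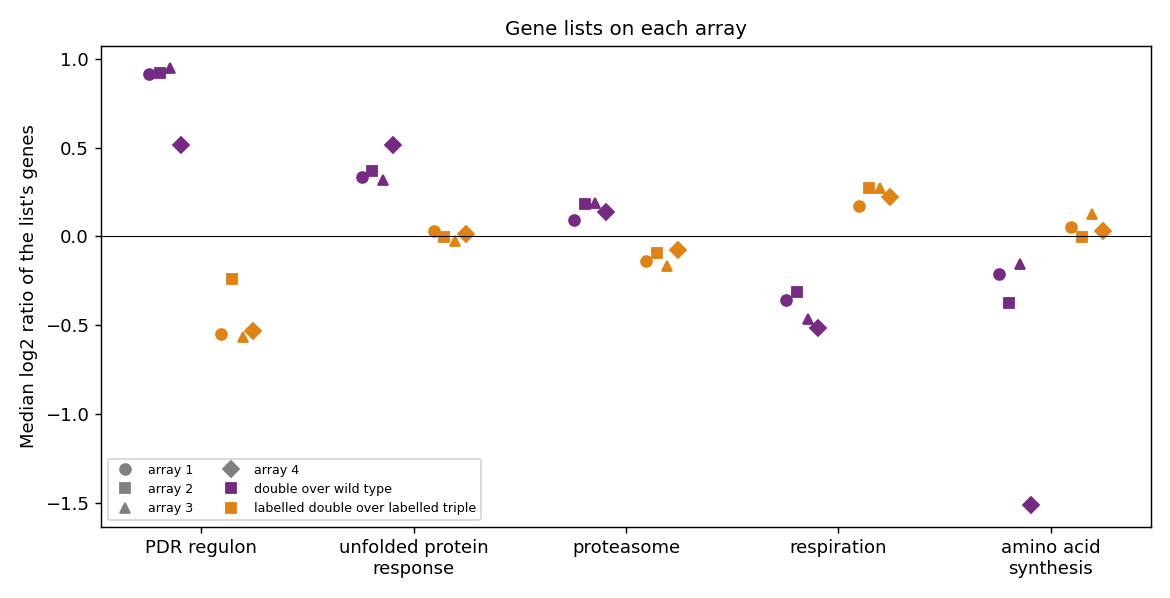
Median log2 ratio of gene lists on each of the 8 arrays, 1 point per array, for the double mutant over wild type and for the channel labelled double over the channel labelled triple mutant. The amino acid synthesis list lies at -1.51 on array 4 and between -0.38 and -0.16 on the other 3 arrays of the comparison with wild type.

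Next to the disrupted PDR5, ATG40 (YOR152C), a receptor for autophagy of the endoplasmic reticulum, rose 2.6-fold in the double mutant (1.38 ± 0.292, SD, n = 4; adjusted p = 0.000406). SLP1 on the other side had a log2 ratio of 0.25 (adjusted p = 0.0228), a call lost without array 1 (0.25), array 2 (0.22) or array 2 of the other comparison (0.25). The neighbours of YOR1 and PDR1 stood between -0.05 and -0.00 (PXR1 -0.04, BGL2 -0.05, ERG4 -0.01, PUF4 -0.00). Of the marker genes, LEU2 had a log2 ratio of -0.76 (adjusted p = 0.0195), a call lost without array 1 (-0.75). LYS2 had -0.77 (adjusted p = 0.0604) and was called lower without array 4 (-0.42; adjusted p = 0.01). URA3 had -0.09. TRP1 stood well above background in 6 of 16 channel measurements, and HIS3 and SUC2 in 0 of 16. No chromosome was shifted as a whole in either comparison. Medians lay between -0.03 and -0.00 against wild type (smallest camera adjusted p = 0.916) and between -0.02 and 0.01 against the triple mutant (camera adjusted p = 1).

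The comparison of the double with the triple mutant asks which transcripts depend on PDR1. As labelled, PDR regulon genes were lower in the channel labelled double mutant, on the arrays where PDR1 itself was. With the sign turned, these genes would be lower in the strain without PDR1. ICT1 was 3.7-fold lower in the channel labelled double mutant (log2 ratio -1.89 ± 0.297, SD, n = 4; adjusted p = 1.81e-05), and RSB1 3.56-fold lower (-1.83 ± 0.34, SD, n = 4; adjusted p = 0.000196). GRE2 was 3.1-fold lower (-1.63; adjusted p = 0.00105) and YOR1 3.17-fold lower (-1.67 ± 0.189, SD, n = 4; adjusted p = 1.81e-05). PDR16, a phosphatidylinositol transfer protein, was 2.16-fold lower (-1.11; adjusted p = 0.000679), and SNQ2 had -1.28, a call lost without array 1 (-1.17), array 3 (-1.28) or array 4 (-1.32). Of the 21 genes of the regulon 9 were lower and 1 higher in the channel labelled double mutant (13 and 2 when adjusted over the list alone). The median was -0.52 (camera adjusted p = 1.99e-11; adjusted p = 0.0857 with an estimated correlation). The exception was PDR15, an ABC transporter gene close in sequence to PDR5, with a log2 ratio of 0.56 (adjusted p = 0.00204) and thus the same sign in both comparisons as labelled. PDR5 had a ratio of -0.14 (adjusted p = 0.565). The list's median was -0.55, -0.57 and -0.53 on arrays 1, 3 and 4 and -0.24 on array 2.

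Respiration genes were higher in the channel labelled double mutant: 5 of 35 were called, 28 when adjusted over the list alone. The median log2 ratio was 0.27 (camera adjusted p = 1.07e-19; adjusted p = 0.158 with an estimated correlation). Examples are RIP1 of complex III (0.41), COX4 of cytochrome c oxidase (0.34) and SDH1 of succinate dehydrogenase (0.34). Their calls were lost without any 1 of the 4 arrays of this comparison, and that of SDH1 also without array 1, 2 or 3 of the comparison with wild type. In the tricarboxylic acid and glyoxylate cycle the median was 0.17 (camera adjusted p = 4.42e-05; adjusted p = 0.465 with an estimated correlation). MDH2, the cytosolic malate dehydrogenase, was the 1 gene of 20 called higher (0.91), 8 when adjusted over the list alone. Proteasome genes were lower in the channel labelled double mutant, with a median of -0.11 (camera adjusted p = 1.61e-09; adjusted p = 0.0857 with an estimated correlation). RPN4 was the 1 gene of 32 called, 4 when adjusted over the list alone, at -0.73 (adjusted p = 0.0367), a call lost without array 1, 3 or 4 (-0.71, -0.65 and -0.63) and without array 1, 2 or 3 of the comparison with wild type (-0.73). With the sign turned, respiration genes would be higher and proteasome genes lower in the triple mutant than in the double mutant.

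Ribosome biogenesis genes (median -0.10, camera adjusted p = 1.92e-06; adjusted p = 0.465 with an estimated correlation) and ribosomal protein genes (median -0.06, camera adjusted p = 3.72e-05; adjusted p = 0.576 with an estimated correlation) shifted slightly, with 0 genes called. Amino acid permeases had a median of 0.09 (camera adjusted p = 0.00784; adjusted p = 0.549 with an estimated correlation) and 1 called gene, SAM3 (0.54; adjusted p = 0.00226). The list passed no longer without array 2 or array 4, with a highest adjusted p of 0.054. Mating-type genes (median -0.08, camera adjusted p = 0.034; adjusted p = 0.261 with an estimated correlation) and sporulation genes (median -0.06, camera adjusted p = 0.0373; adjusted p = 0.465 with an estimated correlation) had 0 genes called, and the sign of the sporulation list's median turned with median centring (0.06). The mating-type call was lost without array 3 and in 4 further settings, and the sporulation call without array 4 and in 6 further settings. The unfolded protein response list had a median of 0.02 (camera adjusted p = 0.891) and the amino acid synthesis list 0.04 (camera adjusted p = 0.263). With the sign turned, each median of this paragraph changes sign.

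Of 103 genes called in this comparison, 68 were higher and 35 lower in the channel labelled double mutant. The 13 that differed at least 2-fold were all lower in it, and 947 genes had an unadjusted p below 0.05. With the sign turned, the 68 would be lower and the 35, the 13 among them, higher in the double mutant than in the triple mutant. The highest as labelled were TPO2, a polyamine transporter gene (0.97), PRY1, a sterol-binding secreted protein (0.93), MDH2, YNL018C (0.81), AQR1 (0.80), TIP1 (0.77) and ADR1, a transcription factor of genes for non-fermentable carbon (0.68). The calls of these 7 were lost without array 1, 3 or 4 and, except for TPO2, without array 2. Those of MDH2 and YNL018C were also lost without array 1 or 3 of the comparison with wild type. PDR15, FTR1 (0.56) and SAM3 completed the 10 highest, and with the sign turned all 10 would be higher in the triple mutant. Beside the disrupted genes, the lowest as labelled also held YAR066W, YAR068W, YHR214W-A and YHR214W (-1.71 to -1.65), TVS1 (-1.31) and SNQ2. The count was 25, 37, 23 and 23 without arrays 1, 2, 3 and 4, and 67 and 472 without arrays 3 and 4 of the comparison with wild type. It held 8 higher and 22 lower genes from the processed signals and 5 and 16 with median centring. Of 37 named calls 11, PDR1, YOR1, RSB1, ICT1, GRE2 and PDR16 among them, were kept in every planned setting that measured them.

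Most genes called in both comparisons went in opposite directions as labelled, and so in the same direction with the sign turned. Of 68 shared genes 65 were opposite, against 4.51 for lists drawn independently, a value that leaves out that both comparisons hold the double mutant. In 100 simulations without effects, in which both shared the double mutant's values, means of 0 genes were opposite and 0.04 the same. Hardly any gene is called without effects, so these means are no measure for the 65. The covariance of the ratios across genes was 0.00415 in the simulations and -0.0136 as labelled, whose sign turns with the labels. The simulations gave arrays of the same number the same double mutant values, but the numbers do not pair the arrays (r of deviations -0.175 to 0.203). Values of the double mutant, if shared in that way, would add to the agreement of the turned reading. They would work against the opposition as labelled. RSB1, ICT1 and GRE2 are among the 27 that were higher than in wild type and lower as labelled in the other comparison. TPO2, SAM3 and FTR1 are among the 38 of the reverse kind. The 3 with the same sign as labelled were PDR15 (0.50 and 0.56), LDB7, a chromatin remodelling subunit (0.42 and 0.36), and PAU12, a seripauperin gene (0.27 and 0.32). LDB7 and PAU12 were named after their values were seen. Without arrays 1, 3 and 4 of the comparison with wild type the 65 became 38, 33 and 232, and without arrays 1, 2, 3 and 4 of the other comparison 20, 32, 17 and 19.

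**Figure D3:**
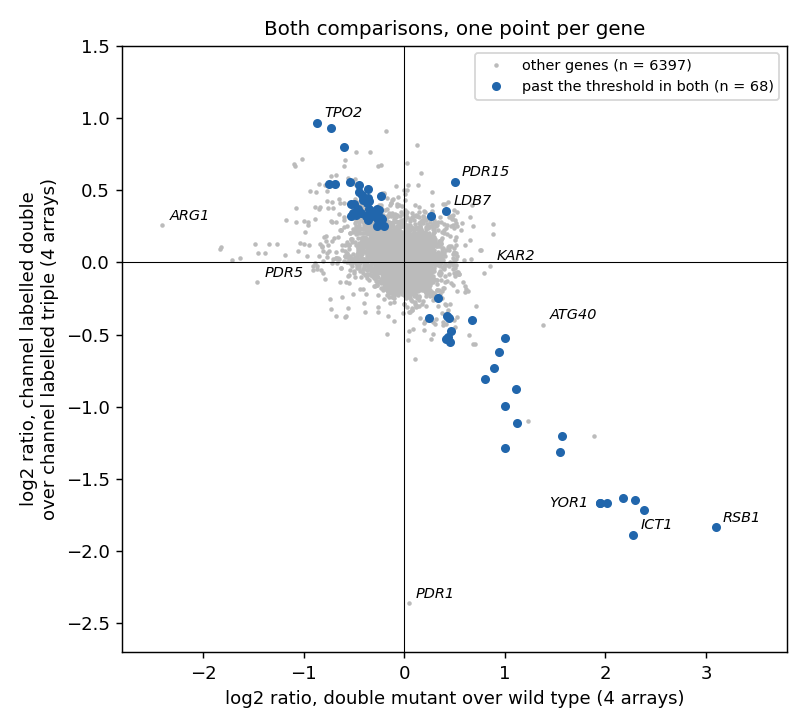
Log2 ratio of each of 6465 genes in the double mutant over wild type (horizontal) against the channel labelled double over the channel labelled triple mutant (vertical), each over 4 arrays. RSB1 stands at 3.09 and -1.83, and PDR1 at 0.05 and -2.36.

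The triple mutant was set against wild type through the double mutant, and what that contrast shows depends on the labels. As labelled, RSB1 would be 30.4-fold higher in the triple mutant than in wild type (log2 ratio 4.93). PDR1 itself would be higher by a fitted log2 ratio of 2.41, although the labels give that strain a disrupted PDR1. PDR1 thus argues against the labelled reading. With the arrays turned, PDR1 was lower, with a fitted log2 ratio of -2.32 ± 0.302 (SE; adjusted p = 0.0286), and so was PDR5, with -1.60 ± 0.132 (SE; adjusted p = 0.00551). RSB1 (1.26; adjusted p = 0.0229), PDR15 (1.06; adjusted p = 0.00313) and KAR2 (0.83; adjusted p = 0.0172) were higher. In that reading the PDR regulon had a median of 0.15 and 2 called genes, 5 when adjusted over the list alone (camera adjusted p = 1.78e-05; adjusted p = 0.214 with an estimated correlation). The unfolded protein response list had a median of 0.41 and 3 called genes of 15, 14 when adjusted over the list alone (camera adjusted p = 6.61e-13; adjusted p = 0.0269 with an estimated correlation). The genes of this paragraph other than PDR1 and PDR5 were chosen after their values were seen. As labelled 573 genes differed, 179 higher and 394 lower (43 and 55 from the processed signals, 35 and 68 with median centring). Turned, 34 did, 24 higher and 10 lower, and 23 genes were called in both readings, whether or not in the same direction. The 573 became 1049 without array 4 of the comparison with wild type and 335, 349, 312 and 274 without arrays 1, 2, 3 and 4 of the other. The 34 became 2, 9, 19 and 193 without arrays 1, 2, 3 and 4 of the former and 2, 3, 1 and 3 of the latter. In those 8 turned fits PDR1 kept its call without array 4 of the comparison with wild type and array 2 of the other, and PDR5 in all but that without array 3 of the other. PDR15 kept its call in all 8, KAR2 without array 2, 3 or 4 of the comparison with wild type, and RSB1 without array 4 of either comparison. The adjusted p of the unfolded protein response list with an estimated correlation lay between 0.0414 and 0.14.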

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

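All tests in this part were chosen after the result was seen, except those of the other sign patterns and splits of the arrays and that of noise between probes. In groups of 4 arrays, 22 of 146 values or list medians had 1 array far from the other 3, and chance gives about 1 in 20 of such groups.

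In the double mutant against wild type, array 4 stood apart from the range of the other 3 arrays as follows. The log2 ratio of SNZ1 was -4.34 (others -1.16 to -0.88), of ARG3 -3.61 (-1.29 to -0.83), of ARO5 -3.33 (-0.88 to -0.78) and of ARG4 -3.01 (-0.86 to -0.72). It was also low for PHO84, at -1.51 (-0.70 to -0.58), MFA2, at -1.12 (-0.34 to -0.20), and CIT1, at -0.68 (-0.29 to -0.21). The subtelomeric genes YAR068W and YHR214W-A were less raised on it, at 1.15 (2.22 to 2.36) and 1.06 (2.17 to 2.28). The list medians on array 4 were -1.51 for amino acid synthesis (-0.38 to -0.16), -1.10 for sulfur and methionine genes (-0.12 to -0.01), -0.74 for amino acid permeases (-0.14 to -0.02) and 0.51 for the PDR regulon (0.91 to 0.95). On array 3 PDR12 was at -0.62 (-0.30 to -0.23) and the sterol synthesis gene ERG27 at 0.44 (0.16 to 0.20), and on array 2 the glycolytic gene TDH1 was at 0.0328 (0.33 to 0.37).

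In the comparison with the triple mutant, as labelled, array 2 had the smallest ratio of PDR1, -1.12 (-2.88 to -2.63), and of the PDR regulon's median, -0.24 (-0.57 to -0.53), and was the array with the lowest Cy3 signal. On array 3 ADR1 was at 0.85 (0.60 to 0.63) and COX4 at 0.43 (0.30 to 0.32). On array 4 the heme oxygenase gene HMX1 was at -0.83 (-0.46 to -0.39), and on array 1 the median of the amino acid permeases was 0.0883 (0.12 to 0.13).

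The first pattern weighed was the low PDR1 signal in the channel labelled double mutant. If the labels were right and signal merely remained at the disrupted gene in the triple mutant, PDR1 in the channel labelled double mutant would lie in that strain's range on the other arrays, but 8 of 8 percentiles lay below it, which argues against this. That the strain labels of the channels are reversed on the double vs triple arrays requires PDR1 signal in the channel labelled triple mutant, and 8 of 8 values there stood well above background. Reversed labels are therefore a candidate explanation. YOR1 goes the same way, at percentiles of 87.5 to 90.4 in the double mutant beside wild type. Here it lay at 59.7 to 70.2 in the channel labelled double mutant and at 85 to 89.5 in the channel labelled triple mutant. Both genes argue against the strain labels of these channels. Whether labels, dyes or RNA samples were exchanged stays open.

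The second pattern was the far lower amino acid synthesis genes on array 4 of the comparison with wild type. Noise between spots is argued against by the deviations of both probes of these genes, which correlated across genes at r = 0.993 (genes are not independent replicates). Wild-type RNA in the double mutant's channel of array 4 would bring ratios nearer to 0, so such RNA alone would not give the pattern. On array 4, 23 of 23 amino acid synthesis genes called without it lay farther from 0. These genes were all lower without array 4, so this count restates the pattern and is no separate test. Of other genes called without array 4, 4 of 14 unfolded protein response genes, tested first, and 13 of 17 PDR regulon genes lay nearer to 0, so such RNA beside another cause is not excluded. That the cultures of array 4 were in another nutritional state was not tested, since the lower value of 41 of 41 genes of the list on array 4 than on each of the other 3 arrays is the pattern itself, and it stays open, as the labels do not describe the cultures.

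The third pattern was that the arrays of the comparison with the triple mutant parted by dye orientation: ratios correlated across genes at r = 0.789 between arrays 1 and 3 and 0.735 between arrays 2 and 4, but at -0.072 to 0.341 across orientations. A dye bias common to all 8 arrays is argued against by the correlation of r = 0.0997 between the dye components of both comparisons. In the comparison with wild type the component did not repeat between arrays 1 and 2 and arrays 3 and 4 (r = 0.0511), so noise there weakens this argument. The main fit holds a common dye term, and with a dye term per comparison 588 and 110 genes were called. Different RNA pairs on arrays 1 and 3 and on arrays 2 and 4 may account for it, with r = 0.747 between the dye components of arrays 1 and 2 and of arrays 3 and 4, but this cannot be told apart from a dye bias of these labellings, since each orientation would carry its own RNA pair.

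With the signs of the arrays changed in all 8 ways, 1 pattern, the real one, gave as many genes in each comparison: 530 against wild type (highest other 31) and 103 against the triple mutant (highest other 1). These 8 patterns are too few for a share under 0.05. For the triple mutant against wild type through the double mutant, 34 splits of the 8 arrays were fitted. The real one alone gave 573 genes as labelled (highest other 0) and 34 with the arrays turned (highest other 0). The other splits mix both comparisons, so real differences add to their spread and lower their counts. The labels also do not say whether the arrays are separate cultures, and the turned sign was chosen after seeing the data. These counts therefore do not exclude a chance division of the arrays. The split that coincides with dye orientation could not be fitted.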

How the results depend on the processing

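Settings chosen after seeing the data were the averaging of arrays 1 and 3 and of arrays 2 and 4, a dye term per comparison, and the turned sign of the comparison with the triple mutant. The counts of called genes were 530 (against wild type), 103 (against the triple mutant) and 573 (triple mutant against wild type), with 65 shared opposite genes. With processed signals they were 36, 30, 98 and 16, and 23 genes in place of 13 differed at least 2-fold from the triple mutant. With median centring they were 54, 21, 103 and 15, with 18 in place of 31 genes at least 2-fold against wild type. The 4 arrays of a comparison alone gave 25, 1250 and 21 shared, with 17 at least 2-fold. Averaging the dye-swap pairs (arrays 1 and 2, arrays 3 and 4) gave 352, 27 and 20 shared, and averaging arrays 1 and 3 and arrays 2 and 4 gave 28, 21, 87 and 14 shared, with 17 at least 2-fold. Dye-swap pairs as random blocks gave 180 against the triple mutant and 104 shared. Array weights gave 330, 2587, 945 and 224 shared, and a PDR5 log2 ratio of -0.14 against the triple mutant then passed (adjusted p = 0.0385). Turning the sign left 34 genes for the triple mutant against wild type and 3 opposite genes. Leaving out each array gave 202 to 825, 23 to 472, 274 to 1049, and 17 to 232 shared, with 19 to 46 at least 2-fold against wild type. The cause was not tested. The fits on fewer arrays or averages have fewer residual degrees of freedom, which does not account for higher counts, such as 1250 and 2587 against the triple mutant. In those 2 fits the arrays of the comparison with wild type had no part, or less part, in the estimated spread. Their weights were 0.158 to 0.801, and those of the other comparison 0.851 to 5.68.

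With replicate numbers as a block, the triple mutant against wild type had 332 genes; the other comparisons could not be fitted with that fixed block, and with a random block they had 571 and 109 genes. The numbers do not pair the arrays (r of deviations -0.175 to 0.203).

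Of 10 and 9 shifted lists, 2 and 0 passed with an estimated correlation. By fry 9 and 3 lists passed, of which 7 and 3 were among the shifted ones. Against wild type 8 lists kept their call in each of 23 other settings, and against the triple mutant 6 did. The sporulation list's median against the triple mutant reversed to 0.0555 with median centring. Of the other comparisons of single genes and lists with an alternative, 3265 were the same, 700 weaker, 59 stronger and 43 moved. Scaling between arrays (Aquantile) changes brightness and not ratios. It could alter no result, so its place among the 23 settings and the 3265 tests nothing. The authors' normalized table was not run. At PDR1, the channel labelled double mutant was below background, so its fold is a lower bound.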

Other observations

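All tests in this part were chosen after the result was seen. The lower transcripts of respiration in the double mutant extended to a list of 56 mitochondrial ribosomal protein genes put together afterwards: 43 were lower than in wild type and 0 higher, with a median log2 ratio of -0.30 (-0.24, -0.32, -0.28 and -0.34 on the 4 arrays; camera p = 2.65e-30, p = 0.0012 with an estimated correlation, p = 5.72e-06 by fry, all from limma). In the channel labelled double over the channel labelled triple mutant 11 of these genes were higher and 0 lower, with a median of 0.24 (camera p = 4.65e-33, p = 0.000973 with an estimated correlation), and with the sign turned these 11 would be higher in the triple mutant. HAP4, the activator subunit for respiratory genes, had a log2 ratio of -0.22 in the double mutant (adjusted p = 0.145), which leaves open whether its transcript was lower.

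RPN4, the transcription factor of proteasome genes and itself 1 of the 32 genes of the proteasome list, had log2 ratios of 0.89 against wild type and -0.73 (adjusted p = 0.0367) against the triple mutant as labelled, where it was the 1 member called. The other 31 genes had medians of 0.13, with 4 called, and -0.11, with 0 called (unadjusted camera p = 1.68e-08 and 1.04e-09, and p = 0.00914 and 0.00663 with an estimated correlation). The whole list lost its call in both comparisons with an estimated correlation (adjusted p = 0.0783 and 0.0857), and RPN4's second call was lost in 6 of the 8 fits that left out an array. With the sign turned, RPN4 and the proteasome genes would be lower in the triple than in the double mutant. That RPN4 and the proteasome genes shift together is a hypothesis found and tested on the same data.

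GCN4, the activator of amino acid synthesis genes, had a log2 ratio of -0.41 in the double mutant against wild type (adjusted p = 0.0128), and PDR3, the paralog of PDR1, of 0.56 (adjusted p = 0.0111) and of 0.23 against the triple mutant as labelled (adjusted p = 0.319), a sign that turns with the labels.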
